A study of Homo sapiens with 2 samples.

How the data were processed

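The deposited files hold raw UMI counts per gene and cell barcode for 2 single-cell libraries of day 30 forebrain organoids, 1 from a line with an introduced DYRK1A variant and 1 from wild-type cells. Per the labels' protocols, organoids were dissociated to single cells, fixed in paraformaldehyde, stored frozen, and processed on the 10x Chromium platform with a single-cell 3' kit, so each count stands for 1 tagged RNA molecule near the 3' end of a transcript. Fixation and storage can cost RNA and can let RNA leak between cells. Per the file headers, the counts were made with Cell Ranger 7.1.0, while the submitters' processing notes name Cell Ranger 8.0.0, Scanpy 1.10.3, Seurat without a version and the build GRCh38, with no role or order. The annotation release was not given in the sources used here. The least UMI total of a deposited barcode was 500 in both libraries, so barcodes had already been selected, by a step not given in the sources used here. The deposited counts carry no normalization. All 36601 genes of the matrices were read, and gene positions were taken from GENCODE 29 by gene ID.

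Each library was 1 sample. The series design states 2 replicates per condition, but each genotype had 1 matrix, barcodes carried 1 common suffix and nothing mapped cells to replicates. Cells are not replicates, so no test between genotypes was run and no p-value is given. Differences are between 2 libraries that also differ in depth and may differ in culture, fixation and handling.

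The choices below were fixed before the data were examined, except where stated. Cells with at least 1000 UMIs, at least 500 genes and at most 20% mitochondrial UMIs were kept. Doublets were scored with Scrublet in scanpy 1.11.5 within each library at an expected rate of 10%. Removal of automatic calls, the rule set first, did not work, since the automatic threshold called 1864 of 9543 variant barcodes (19.5%) and 1 of 22045 wild-type barcodes (0.00454%). A second rule set beforehand was therefore used, which removes the 10% of barcodes with the highest score in each library, 885 and 2150 barcodes because of ties, and the automatic calls became a setting added for comparison. No correction for free RNA was made.

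Both libraries were clustered together without batch integration, on 3000 variable genes, 30 components, 15 neighbours and Leiden clustering at resolution 1, which gave 22 clusters. Clusters were named from marker sets fixed beforehand. The naming rule was set after the data were seen. A marker counted as raised when its log2(CPM + 10) lay at least 0.5 above the mean of the 2 library profiles and at least 10% of the cluster's cells held it, and a name needed at least 3 raised markers. Neuronal names also needed a radial glia score of at most -0.5, and other names a pan-neuronal score of at most -0.5. A score is the mean log2 distance of a set's markers from the mean of the 2 library profiles, negative when below it. These rules left 12 clusters unnamed, whose shares are given for each library.

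For each library and class, raw counts were summed and divided by the class total to give CPM. A ratio of 2 sums has an exact conditional binomial 95% interval, a CPM an exact Poisson interval and a share of cells an exact Clopper-Pearson interval. These cover counting error only. A sum of 0 was set to a floor of 3 counts. Classes were compared when each library had at least 200 cells in them. For shares of cells with a UMI and for cell cycle phases, every cell was thinned to 2000 UMIs and shallower cells were left out. Phases came from scanpy's cell cycle scores.

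Gene lists were fixed beforehand, 27 pathway or function lists and 20 marker sets. A list's value is the median log2 CPM ratio over members with at least 10 CPM in either library. It is given with its percentile among 10000 random lists of the same size matched on mean expression, as a description of these 2 libraries. Marker sets with fewer than 3 measured members have no median. Named genes were the 10 with the largest and the 10 with the smallest log2 ratio among genes with at least 50 CPM in either library, with an interval that excludes 1 and the same direction after thinning and after median-ratio scaling. They were taken for kept cells, radial glia-like cells and excitatory neuron-like cells. Clone names, mitochondrial and ribosomal protein genes and genes that report sex were left out by the rule. Other genes named in the text are members of the fixed lists, used as examples.

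The ratio step was tested on simulated data over all kept cells with 10794 genes. Its intervals covered the true ratio for 94.9% of genes, and 100% of 100 genes with a log2 change of 1 and 100% of 100 genes with a log2 change of 2 were recovered with the right sign. The simulated counts were Poisson draws, the model that the intervals assume, without variation between cells, cultures or libraries. This checks the calculation only. Other settings fixed beforehand were a stricter cell filter (at least 2000 UMIs, 1000 genes and at most 10% mitochondrial UMIs), no cell filter, doublets kept, TMM scaling with edgeR 4.0.16, median-ratio scaling, totals without mitochondrial and ribosomal protein genes, the mean of single-cell CPM, thinning, other cluster resolutions and gene sets, libraries scaled on their own, list minimums of 1 and 50 CPM, and other depths and thresholds for phases. Settings added after the data were seen were the automatic doublet calls, leaving stress genes out of clustering, and restricting comparisons to named clusters. The scalings shifted log2 ratios by at most 0.07 in any class compared. Clusters of cell subtypes below the named classes, and reads, were not analysed here.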

Results

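Single-cell RNA profiles were measured in human forebrain organoids grown on micropatterned surfaces, at day 30 in vitro, from stem cells of 2 genotypes. Wild-type organoids came from a library whose name cites H9, an established human embryonic stem cell line. The other organoids came from an isogenic line into which a variant of DYRK1A had been introduced, a C-to-T change according to the labels, which do not name the cell line of that library. DYRK1A is a protein kinase known to act on cell cycle exit, and loss of 1 copy of the gene is known to cause microcephaly with intellectual disability. The comparison asks how cell types and gene expression differed between organoids with and without the variant. The series design states 750 organoids per sample, 2 replicates per condition and 3000 organoids in total. The files hold 1 matrix per genotype with no map from cells to replicates, so each genotype counted as 1 library. No difference below has a replicate check, no test between genotypes was possible, and intervals are exact 95% intervals that cover counting error only.

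The DYRK1A variant library held 10996 barcodes and 186085846 UMIs (unique molecular identifiers, each standing for 1 captured RNA molecule), with a median of 12864.5 UMIs per barcode. The wild-type library held 22496 barcodes and 186322802 UMIs, with a median of 6263.5. After filtering, 8658 variant cells and 19895 wild-type cells were kept, with medians of 13940.5 and 6404 UMIs. Of the barcodes, 13.2% in the variant library and 2.00% in the wild type failed the cell filter. Mitochondrially encoded genes took 2.73% of the variant UMIs and 2.78% of the wild-type UMIs.

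DYRK1A RNA was not lower in the variant library. DYRK1A (ENSG00000157540, chromosome 21, positions 37365573 to 37526358 on the plus strand, GRCh38, GENCODE 29) stood at 187 CPM (UMIs of a gene scaled to a common library total; 184 to 189) in the kept variant cells and 160 CPM (158 to 162) in the wild type, a ratio of 1.17 (1.15 to 1.19). The ratio was 1.17 (1.13 to 1.21) in radial glia-like cells, 1.20 (1.05 to 1.39) in intermediate progenitor-like cells and 1.06 (1.01 to 1.12) in excitatory neuron-like cells. A single-base variant need not alter the RNA level and 3' tags do not read the base, so these values do not check the genotype labels. The 15 fixed neighbours of DYRK1A on chromosome 21, 8 of them measured, had a median log2 ratio of -0.06, and 8 measured members of the DYRK family and its partners had 0.03. Both medians lay within the range of matched random lists.

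Named cell classes differed in share between the libraries. Radial glia-like cells, the neural stem cells of the developing cortex, made up 38.7% (37.7 to 39.8) of kept variant cells and 16.3% (15.8 to 16.8) of kept wild-type cells. Cluster 4, with 1647 of the variant cells, was named on 3 raised markers, the least allowed, while cluster 8, with most of the wild-type cells, had 11. Intermediate progenitor-like cells, led by NEUROG2, HES6 and EOMES, made up 3.52% and 1.14%, and excitatory neuron-like cells, with TBR1 and SLC17A6 among their leading genes, 12.7% and 7.11%. The wild-type share of the latter was 2.88% with cell cycle genes left out of clustering and 0.925% with stress genes left out. Inhibitory neuron-like cells numbered 4 of 8658 in the variant (0.0462%, 0.0126 to 0.118) and 2741 of 19895 in the wild type (13.8%, 13.3 to 14.3). Cortical hem-like cells made up 1.29% and 5.84%. Their leading genes included RSPO2, RSPO3 and LMX1A, but also TTR, a member of the choroid plexus marker set. No cluster passed the rules for a Cajal-Retzius-like name with the main settings. Under 8 of 10 other settings such a class was named, with 4.94% and 1.02% under the strict cell filter and 3.21% and 3.10% with libraries scaled on their own.

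Unnamed clusters held 43.8% of variant cells and 55.9% of wild-type cells and differed in kind. Clusters 11 to 15 and 21, grouped because they were mostly wild type, held 37 variant cells (0.427%) and 10022 wild-type cells (50.4%, 49.7 to 51.1). Among marker sets with at least 3 raised members, inhibitory neuron markers scored highest in each, with 4 to 8 raised. They missed the radial glia limit of -0.5 for a neuronal name, with scores from -0.481 in cluster 21 to 0.223 in cluster 14. Cluster 15, the largest, had -0.0728. Profiles of these clusters also lay close to the rest of their own library. Over genes with at least 50 CPM, the standard deviation of the log2 difference from that rest was 0.136 to 0.391. In named clusters it was 0.491 to 1.19. CCNO and TEKT1 were among the leading genes of cluster 13, and TOP2A and MKI67 among those of cluster 14. Clusters 0, 1 and 5, in which mitochondrial transcripts were scarce and GDF15, DDIT3, GADD45A and PMAIP1 were among the leading genes of clusters 0 or 1, held 2935 variant cells (33.9%, 32.9 to 34.9) and 546 wild-type cells (2.74%, 2.52 to 2.98). Clusters 3, 6 and 18 held 9.42% and 2.75%. In clusters 6 and 18 Cajal-Retzius markers scored highest, with 4 raised in each, but both also missed the radial glia limit. Their radial glia scores were -0.498 and -0.237, and EBF1 and EBF3 were among the leading genes of cluster 6. They held 438 and 191 variant cells and 154 and 76 wild-type cells. Most of these unnamed cells came from 1 library, so such a cluster may be that library and not a cell type. Among cells of named clusters alone, radial glia-like cells made up 68.8% and 36.9%, inhibitory neuron-like cells 0.0821% and 31.2%, and excitatory neuron-like cells 22.5% and 16.1%. The higher radial glia-like share in the variant was lost when cells were thinned to 2000 UMIs before clustering (difference -6.51 percentage points, against 22.5), a setting in which 81.4% of variant and 61.2% of wild-type cells were unnamed and no excitatory neuron-like class was named. The directions for intermediate progenitor-like and cortical hem-like cells turned under other cluster settings.

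**Figure D1:**
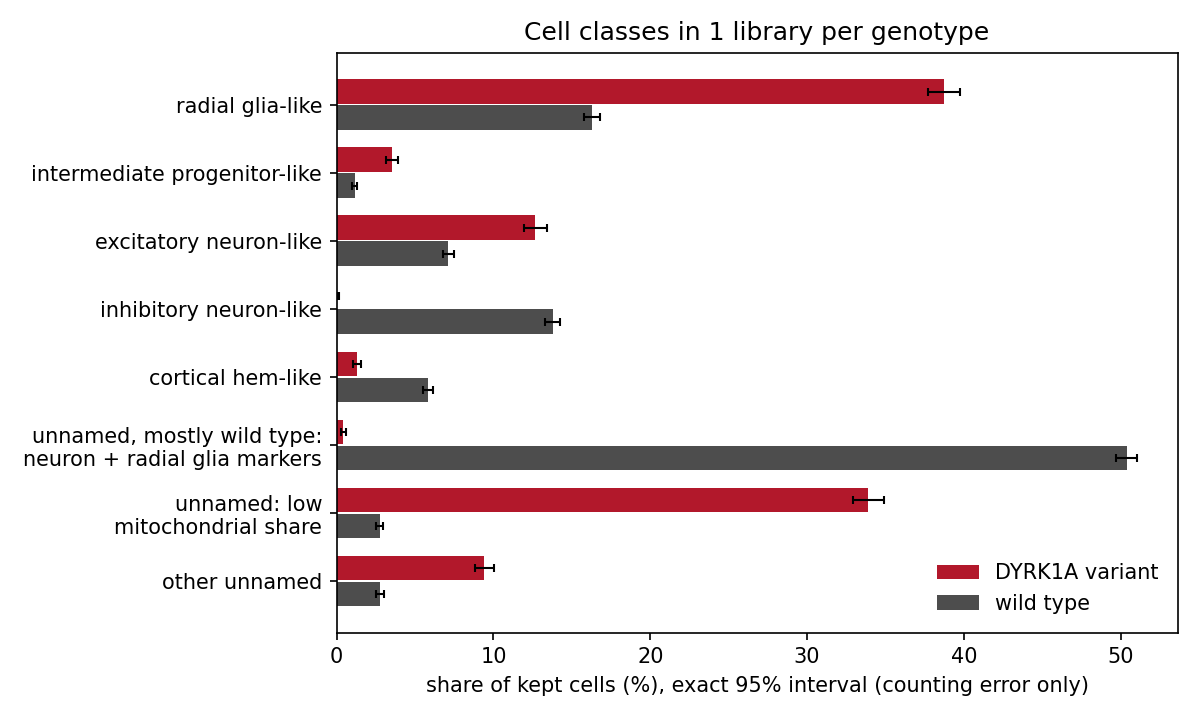
Share of kept cells (x axis, %) in each named class and each group of unnamed clusters, in the DYRK1A variant library (red) and the wild-type library (grey), with exact 95% intervals for counting error. Inhibitory neuron-like cells stand at 0.0462% in the variant and 13.8% in the wild type. Clusters 11 to 15 and 21, labelled neuron + radial glia markers because they missed the radial glia limit of a neuronal name, stand at 0.427% and 50.4%. The low-mitochondrial clusters 0, 1 and 5 stand at 33.9% and 2.74%.

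Most genes of forebrain inhibitory neurons were near absent from the variant library. All 9 measured inhibitory neuron markers were lower in it, 8 of them by at least 1.5-fold, with a median log2 ratio of -6.33, below each of 10000 matched random lists. The 9 summed to 101 CPM in the variant and 922 CPM in the wild type, so not all of them were near absent. In radial glia-like cells 1 of 3 measured markers was higher in the variant, and the 3 summed to 120 and 129 CPM. DLX6-AS1 stood at 0.948 CPM against 473 CPM in the wild type, DLX5 at 0.125 against 65.2, DLX1 at 0.293 against 62.4 and GAD2 at 3.39 against 96.4. DLX1 and DLX5 encode transcription factors of the GABAergic lineage and GAD2 an enzyme that makes GABA. After thinning to 2000 UMIs, 0.774% (0.596 to 0.987) of 8270 variant cells and 50.7% (50.0 to 51.4) of 18366 wild-type cells held a UMI of DLX1, DLX2, DLX5, DLX6-AS1 or GAD2. In radial glia-like cells the shares were 0.60% and 8.13%, at median depths of 16019.5 and 8942 UMIs before thinning. Over cells of named clusters alone the thinned shares were 0.578% and 37.8%. Unthinned shares were 2.49% and 66.1% of kept cells. The thinned set left out 388 variant and 1529 wild-type cells with fewer UMIs.

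Neuronal RNA as a whole was also lower in the variant library. All 14 pan-neuronal markers were lower, with a median of 0.499-fold over kept cells, and 17 of 19 measured synapse genes were lower, with a median log2 ratio of -0.68. NRXN3, a presynaptic adhesion gene, stood at 353 and 1837 CPM and the sodium channel gene SCN2A at 6.13 and 31.6 CPM, while SYP, a synaptic vesicle gene, was higher in the variant at 97.6 against 40.9 CPM. Within excitatory neuron-like cells the median was 1.00-fold for pan-neuronal markers and 1.00-fold for the synapse list. STMN2, a neuronal microtubule regulator, had a UMI in 22.9% of thinned variant cells and 66.0% of thinned wild-type cells. The shares were 27.2% and 52.3% over cells of named clusters alone, and 5.58% and 11.4% in radial glia-like cells.

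**Figure D2:**
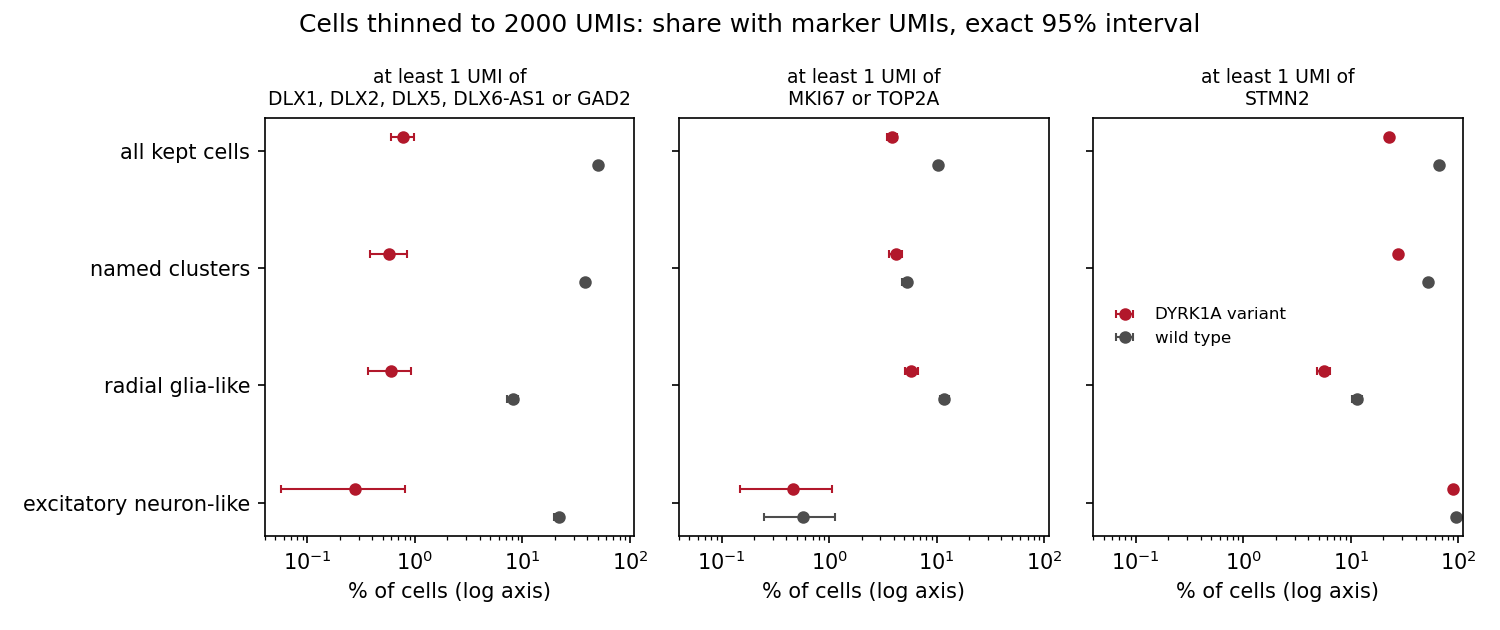
Share of cells (x axis, %, log axis) with at least 1 UMI of inhibitory neuron genes, of MKI67 or TOP2A, and of STMN2, after every cell was thinned to 2000 UMIs, in the variant (red) and wild-type (grey) libraries with exact 95% intervals. The inhibitory neuron genes are seen in 0.774% of variant cells and 50.7% of wild-type cells, and MKI67 or TOP2A in 5.79% and 11.8% of radial glia-like cells.

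RNA of dividing cells was seen in fewer thinned cells of the variant library. A UMI of MKI67 or TOP2A, genes of proliferating cells, was seen in 3.82% (3.42 to 4.26) of thinned variant cells and 10.4% (9.93 to 10.8) of thinned wild-type cells. In radial glia-like cells the shares were 5.79% (5.02 to 6.64) of 3332 and 11.8% (10.7 to 13.0) of 3184, against 0.458% and 0.573% in excitatory neuron-like cells, which do not divide. Phase scores put 9.81% of variant and 17.4% of wild-type radial glia-like cells in G2M and 20.1% and 26.0% in S, while 7.78% and 12.0% of excitatory neuron-like cells were also called G2M. All 54 measured G2M genes were lower in variant radial glia-like cells, with a median log2 ratio of -1.09, and 38 of 39 S phase genes were lower, with a median of -0.58. The G2M median ran from -1.32 with no cell filter to -0.43 with automatic doublet calls removed. Over kept cells the medians were -0.51 and -0.30. TOP2A in radial glia-like cells stood at 62.5 and 187 CPM. Unthinned MKI67 or TOP2A shares in radial glia-like cells were 15.8% and 21.2%. The difference in radial glia-like cells was -6.02 percentage points as reported, -1.97 with doublets kept and -14.0 with no cell filter, each clustered anew, while over kept cells it was -6.55, -6.34 and -6.43. Over cells of named clusters the thinned shares were 4.15% and 5.24% while the unthinned ones were 12.2% and 10.5%.

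Genes of cholesterol synthesis were lower in the variant in each class compared. All 18 members were lower over kept cells, 15 of them by at least 1.5-fold, with a median log2 ratio of -1.04 (0.486-fold), below each of 10000 matched random lists. The medians were -1.09 in radial glia-like, -0.89 in excitatory neuron-like and -0.84 in intermediate progenitor-like cells. HMGCS1, an early enzyme of the pathway, stood at 186 CPM in variant and 610 CPM in wild-type radial glia-like cells, and at 258 and 636 CPM in excitatory neuron-like cells. SQLE, the squalene epoxidase, stood at 95.6 and 236 CPM in radial glia-like cells, and INSIG1, a sterol-regulated inhibitor of the pathway, at 11.5 and 35.5 CPM.

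Stress and p53 genes were higher over the kept variant cells. Of 19 measured genes of the unfolded protein and integrated stress response 16 were higher, with a median log2 ratio of 0.74, and of 20 p53 targets and apoptosis genes 18 were higher, with a median of 0.80. The heat shock and immediate early list had a median of 0.60, with 13 of 15 higher. DDIT3, a transcription factor of the stress response, stood at 264 and 48.8 CPM, HSPA5, a chaperone of the endoplasmic reticulum, at 528 and 229 CPM, and MDM2, a p53 target, at 328 and 130 CPM. Over cells of named clusters the 3 medians were 0.16, 0.34 and 0.10. In radial glia-like and excitatory neuron-like cells the medians were 0.14 and 0.053 for the stress response list and 0.11 and 0.14 for the p53 list. For the heat shock list they were -0.027 and 0.059. The p53 medians and the first stress response median lay above the range of matched random lists, the others within it. The single gene DDIT3 stood at 99.3 and 35.6 CPM in radial glia-like cells and at 105 and 45.7 CPM in excitatory neuron-like cells.

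**Figure D3:**
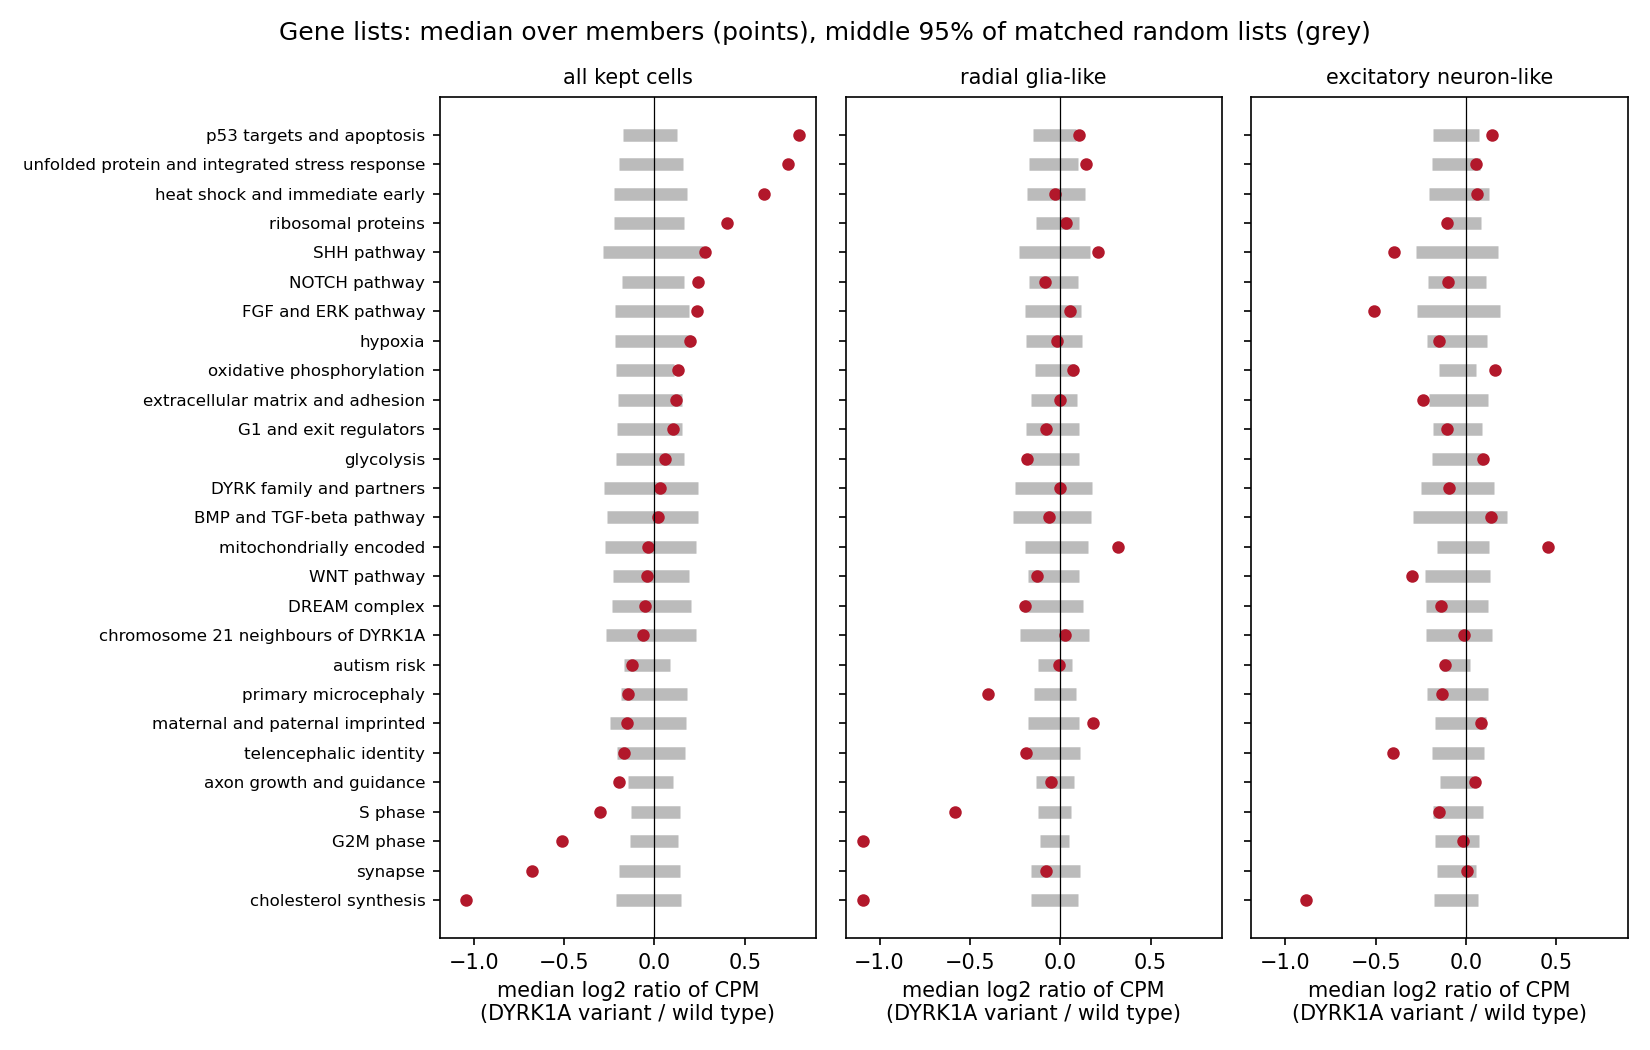
Median log2 ratio of CPM, DYRK1A variant over wild type (x axis), of each fixed gene list over kept cells, radial glia-like cells and excitatory neuron-like cells (points), with the middle 95% of 10000 matched random lists in grey. Cholesterol synthesis lies at -1.04, -1.09 and -0.89 in the 3 panels, and G2M phase at -1.09 in radial glia-like cells.

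Of the 27 gene lists, 8 had a median above the range of matched random lists over kept cells, 5 below it and 14 within it. Ribosomal proteins had a median of 0.40 with 25 of 25 higher, oxidative phosphorylation 0.13, NOTCH pathway 0.24, FGF and ERK pathway 0.24 and SHH pathway 0.28. Some of these medians were not higher within classes. In radial glia-like and excitatory neuron-like cells they were 0.031 and -0.11 for ribosomal proteins, and -0.084 and -0.10 for the NOTCH pathway. The FGF and ERK pathway had -0.51 in excitatory neuron-like cells, below the random range, with 5 of 8 measured genes lower. That median ran from -0.50 to 0.037 under other settings, so its direction was not kept in all of them. Axon growth and guidance had a median of -0.20. Besides the 2 lists around DYRK1A given above, lists within the range were G1 and exit regulators (0.10), the DREAM complex (-0.05), primary microcephaly (-0.15), autism risk (-0.12), telencephalic identity (-0.17), WNT pathway (-0.04), BMP and TGF-beta pathway (0.02), glycolysis (0.06), hypoxia (0.19), mitochondrially encoded genes (-0.04), extracellular matrix and adhesion (0.12) and imprinted genes (-0.15). Mitochondrially encoded genes lay above the range within each class, with medians of 0.32 in radial glia-like, 0.46 in excitatory neuron-like and 0.48 in intermediate progenitor-like cells. Within radial glia-like cells the primary microcephaly list had a median of -0.40, with 18 of 21 genes lower, but of -0.019 with doublets kept.

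Over kept cells, 17 of the 20 genes picked by a fixed rule of size were also among the leading genes of a cluster, so their ratios may partly follow cluster shares. Those higher in the variant included GDF15, a stress-induced cytokine (183 and 15.6 CPM, 11.7-fold), P2RX4, MROH8, PIPOX, PTGDS, CTC1, NEAT1, PLCG2 and GRIN2A. NEAT1, a long noncoding RNA of nuclear paraspeckles, stood at 1185 and 183 CPM. Those lower in the variant were DLX5, DLX6-AS1, DLX1, GAD2, TTR, SEMA3E, ZNF506, KCNMB2, KIRREL3 and CNTN5. TTR, the thyroid hormone carrier made by choroid plexus and a leading gene of the cortical hem-like cluster, stood at 0.690 and 60.8 CPM. Over cells of named clusters alone several of the higher genes differed less, with log2 ratios of -0.13 for CTC1, 0.066 for PIPOX, 0.77 for P2RX4, 0.85 for PLCG2, 1.00 for MROH8 and 1.83 for GDF15.

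Radial glia-like cells differed in regional and glial genes. Different clusters held most of the class in each library. Clusters 2 and 4 held 1107 and 1647 of the 3352 variant cells, and cluster 8 held 2133 of the 3236 wild-type cells, so 8 of the 20 genes below also define a cluster. SLC1A3, a glutamate transporter of radial glia, stood at 47.2 CPM in the variant and 328 CPM in the wild type, and FABP7, a radial glial fatty acid carrier, at 276 and 677 CPM. Overall 13 of 15 radial glia markers were lower, with a median log2 ratio of -0.44, VIM standing at 0.781-fold. LHX2, a selector of cortical identity, stood at 40.0 and 106 CPM. The telencephalic identity list had a median of -0.19, with 9 of 14 genes lower. Of 6 measured cortical hem markers 5 were higher, with a median of 0.68, among them WLS, which is needed for WNT secretion, at 444 and 145 CPM. The other genes by the rule that were higher in the variant were ANKRD34B (13.0-fold), HTR2C, PMEL, PTGDS, APOE (124 and 20.2 CPM), LHX5-AS1, ADAMTSL1, PUS7L, LRMDA and NEAT1. Those lower were CRH (3.33 and 105 CPM), MGAT4C, MOXD1, RGS6, SLC1A3, CEBPZOS, NFIA, STMN4, C1orf61 and TMEM158. NFIA, a transcription factor of the switch to gliogenesis, stood at 11.8 and 61.7 CPM.

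Excitatory neuron-like cells formed cluster 9 in both libraries, with 1097 variant and 1414 wild-type cells. Genes higher in the variant were GPR149 (10.2-fold), DLC1, DGKB, NNAT, LHX5, PUS7L, NPFFR2, ZFHX4-AS1, LHX5-AS1 and KCND2. NNAT, an imprinted gene of developing neurons, stood at 2440 and 525 CPM, and LHX5, a transcription factor of Cajal-Retzius cells and the cortical hem, at 90.1 and 20.5 CPM. TBR1, a transcription factor of early cortical neurons, stood at 182 and 108 CPM. Genes lower in the variant were DLX6-AS1, GAD2, ZNF506, KCNMB2, NTM, SOX2-OT, RBFOX1, PDE1A, SIX3 and MPPED2. Of these, DLX6-AS1, GAD2, KCNMB2 and SIX3 were also among the leading genes of inhibitory neuron-like cluster 19. With cell cycle genes left out of clustering, the wild-type excitatory neuron-like class fell to 572 cells. The wild-type inhibitory neuron-like class then rose from 2741 to 3735 cells. The make-up of the wild-type class may thus enter these ratios, which was not tested. DLX6-AS1 had 0 UMIs in the variant cells and 339 CPM in the wild type. With the floor of 3 counts its log2 ratio was -10.95, and the upper end of its interval was -10.65. A UMI of an inhibitory neuron gene was seen in 21.7% of thinned wild-type and 0.275% of thinned variant excitatory neuron-like cells. The wild-type share was 8.58% with the strict filter, 8.97% with no filter, 11.3% with doublets kept and 6.12% with automatic doublet calls removed. Several lower genes also differed less under other filters or doublet rules, each clustered anew, with log2 ratios at their weakest of -0.27 for MPPED2 (-2.48 as reported), -0.76 for SIX3 (-2.67), -0.82 for KCNMB2 (-3.90), -0.95 for RBFOX1 (-2.93) and -1.23 for SOX2-OT (-3.21). The telencephalic identity list had a median log2 ratio of -0.40, with 9 of 13 genes lower.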

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

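Comparisons between classes and unused barcodes gave the results in this part, and none of the differences between classes was tested, because each genotype had 1 library. The SHH pathway list differed in direction between classes. Its median log2 ratio, variant over wild type, was 0.21 in radial glia-like cells, above the range of matched random lists, and -0.40 in excitatory neuron-like cells, below that range, where all 8 measured genes were lower. The latter was -0.042 at its weakest, with cells thinned to 2000 UMIs. PTCH1, a receptor and target gene of the pathway, stood at 120 and 70.3 CPM in radial glia-like cells and 43.0 and 56.3 CPM in excitatory neuron-like cells. The glycolysis list also differed in direction, with a median of -0.18 in radial glia-like cells and 0.10 in excitatory neuron-like cells. The latter ran from -0.065 to 0.16 under other settings, so this difference in direction was lost under some of them. Barcodes that failed the cell filter, which the comparisons of the report left out, made up 13.2% of the variant barcodes and 2.00% of the wild-type barcodes. In them GDF15 stood at 81.9 CPM in the variant and 14.4 CPM in the wild type.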

How the results depend on the processing

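Settings that restricted cells to named clusters, removed automatic doublet calls or left stress genes out of clustering were chosen after seeing the data. No paired analysis was possible because each genotype had 1 library and no replicate numbers, and no library could be left out. Of 1607 recomputed values over 156 results, 1191 moved by less than their error from counting or from resampling list genes, 396 moved further and 20 changed sign from a main value larger than that error. With smaller values counted, 41 of the 156 results did not keep their sign in every setting, 35 of them list medians. Of 63 gene ratios 62 kept their sign under the 9 or 10 alternatives run for each, the exception being CTC1 over kept cells (-0.13 with named clusters). Part of this was fixed in advance. The rule for named genes required the same direction after thinning and after median-ratio scaling. The scalings also shifted log2 ratios by at most 0.07, too little to turn any of these genes. The cause was not tested for any value below, except that thinning and filters remove cells by construction.

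The DYRK1A log2 ratio of 0.22 was 0.20 with median-ratio factors, 0.28 without mitochondrial and ribosomal genes, 0.36 as a mean of cell CPM, 0.38 with cells thinned to 2000 UMIs and 0.17 with named clusters. The stress response list, 0.74 over kept cells, was 0.19 with named clusters and the same genes, while the G2M list over kept cells stayed within its resampling error.

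The inhibitory neuron-like difference of -13.7 percentage points was -16.0 with the strict filter, -15.1 with no filter, -13.2 with automatic doublet calls, -12.6 at resolution 2, -18.5 without cell cycle genes, -14.3 with libraries scaled on their own, -15.5 thinned and -31.1 in named clusters. The radial glia-like difference of 22.5 points was 19.6 with the strict filter, 11.6 with no filter, 20.5 with doublets kept, 15.5 with automatic calls, 19.5 at resolution 0.5, 13.0 at resolution 2, 16.6 with libraries scaled on their own, 14.5 without stress genes, 32.0 in named clusters and -6.51 thinned. The unnamed difference turned to 20.2 thinned, the intermediate progenitor-like one to -2.82 without stress genes, and the cortical hem-like one to 0.809 with automatic calls, 3.76 at resolution 2 and 1.83 without stress genes. The MKI67 or TOP2A difference of -6.55 points was -7.40 at full depth, -8.92 at 4000 UMIs and -1.09 in named clusters, where the S phase difference turned to 0.398.

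In excitatory neuron-like cells 3 list medians larger than their resampling error changed sign, of which primary microcephaly and autism risk lay within the range of matched random lists. Primary microcephaly (-0.14) was 0.066 with the strict filter, 0.011 with no filter, 0.059 with doublets kept and 0.019 by cell means. Autism risk (-0.12) was 0.046, 0.027 and 0.037 with the strict filter, no filter and doublets kept, and 0.030 with automatic calls. Oxidative phosphorylation (0.16) was -0.0297 with the strict filter, -0.042 with doublets kept, -0.027 with automatic calls and -0.00907 by cell means. Depth limits the wild type most, where 5321 of 19895 kept cells held under 4000 UMIs against 887 of 8658 in the variant.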

Other observations

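The tests of explanations in this part were chosen after the results were seen. Some markers of other brain regions and early neurons also differed. Over kept cells 5 of 6 measured Cajal-Retzius markers were higher in the variant, with a median log2 ratio of 0.78 and a percentile of 99.8, EBF2 standing at 60.6 and 33.6 CPM, although CALB2, another marker of that set, was at 3.10 and 17.6 CPM. The median for these markers was 0.43 within excitatory neuron-like cells. Of 3 measured diencephalon and hypothalamus markers in excitatory neuron-like cells, LHX9 stood at 81.7 and 22.7 CPM and BARHL1 at 17.7 and 2.04 CPM, while TCF7L2 was lower at 31.4 and 44.2 CPM. Cortical hem markers had a median of -1.04 over kept cells against 0.68 within radial glia-like cells. Medians over kept cells were -0.09 for radial glia, 0.26 for intermediate progenitor, -0.20 for excitatory neuron, -0.46 for choroid plexus, -0.62 for eye field and retina, and 0.68 for midbrain and hindbrain markers, the last 3 from 3 genes each. Of these, the radial glia, excitatory neuron, and midbrain and hindbrain medians lay within the range of matched random lists.

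Within the variant library, the low-mitochondrial clusters 0, 1 and 5, pooled, were set against radial glia-like cells. GDF15 stood at 516 and 21.9 CPM, ATF3 at 205 and 18.6 CPM, MDM2 at 789 and 137 CPM and PMAIP1, a p53-inducible apoptosis gene, at 55.7 and 6.62 CPM. The heat shock and immediate early list had a median log2 ratio of 1.63, the p53 list 0.92 and the WNT pathway list -1.35. The clusters differed, with stress response medians of 1.36, 1.23 and 0.50, p53 medians of 0.77, 1.60 and 0.041 and heat shock medians of 0.54, 2.33 and 2.75 in clusters 0, 1 and 5. The 546 wild-type cells in the same clusters had medians of 1.45 for the stress response list and 0.87 for the p53 list over wild-type radial glia-like cells.

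The near absence of most inhibitory neuron markers from the variant library is the pattern most worth following up. Loss to the cell and doublet filters is argued against, because DLX6-AS1 stood at 2.86 CPM in the removed variant barcodes. A culture, line or library difference other than the variant cannot be told apart from an effect of the variant, because there was 1 library per genotype. An effect of the variant therefore stays open as a hypothesis. Separate cultures of each genotype could tell it from a culture or library difference. A line difference would recur in such cultures, so they could not tell it from the variant.

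About 50.4% of wild-type cells lay in 6 mostly wild-type clusters that scored for inhibitory neuron markers but missed the radial glia limit of a neuronal name. Clusters 6 and 18, mostly variant, missed it too, with Cajal-Retzius markers raised. Profiles of the 6 mostly wild-type clusters lay closer to the rest of their library than those of named clusters did. Cluster 6 also lay close to the rest of its library, with a standard deviation of 0.280. These values were not weighed against the explanations below. Multiplets of intact cells as the whole source are argued against, because the median UMI count was 0.588 times that of wild-type cells in named clusters (5086.5 and 8656). They stay open for a part, because cluster 12 had a ratio of 1.02 and median doublet scores were 0.111 to 0.162 in these 6 clusters against at most 0.101 in named clusters. Free RNA in the droplets stays open too, with cortical hem marker UMIs per cell 2.08 times as high in these clusters as in inhibitory neuron-like cells (3.96 and 1.90). A ratio of at most 2 was set for free RNA and above 3 against it, and the limit against it had first been put at 2, which this ratio passes.

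The low-mitochondrial stress clusters may reflect the state of the cells or their handling. A variant library shallower as a whole is argued against, since its kept cells held 2.18 times the median UMIs of the wild type. That value does not speak to single clusters. Variant cells of clusters 0, 1 and 5 had medians of 15304.5, 6313 and 5764.5 UMIs, against 13940.5 over kept variant cells. Loss of cytoplasm from fixed cells stays open, because ribosomal protein genes, whose RNA is cytoplasmic, had a pooled median log2 ratio of 0.33 over variant radial glia-like cells, just above the upper bound of 0.32 of matched random lists, but 0.28, 0.28 and 0.40 in clusters 0, 1 and 5, each within its range. Poorer cells in the variant library stay open, as 6.59 times the share of barcodes failed the filter there. Stress during culture or dissociation and an effect of the variant stay open, as neither was tested.

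Some genes differed by at least 4-fold in the same direction in radial glia-like, excitatory neuron-like, intermediate progenitor-like and stress cluster cells alike. Among 9091 genes with at least 10 CPM in each of the 4 comparisons there were 12 such genes, 4 higher and 8 lower in the variant, picked after their values were seen. ZNF736 on chromosome 7 had 0 UMIs in variant radial glia-like cells against 22.9 CPM in the wild type. ZNF667-AS1 on chromosome 19 stood at 0.103 and 15.2 CPM and IRAK4 on chromosome 12 at 17.8 and 3.94 CPM in radial glia-like cells.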
